A study of Mus musculus with 6 samples.

How the data were processed

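Single-cell RNA was measured in 6 libraries from adult mouse brain, 2 per genotype group (control with floxed Gja1 alleles, GlastiKO and ECiKO). Per the labels, cells of cortex and subventricular zone were digested for 30 minutes at 37 degrees, sorted by flow cytometry into endothelial and neural stem and progenitor fractions, and made into libraries with the 10x Chromium 3′ kit version 3.1. The deposited values are raw UMI counts per gene and cell barcode, without normalization, for 32285 genes and 7433 barcodes that the authors' pipeline had called as cells. The labels' protocols name Cell Ranger 5.0.0 with the mm10 genome, while the submitters' processing notes list Cell Ranger 2.1.1 and Seurat 4, so the version is stated in 2 ways. The numbers of barcodes equal the estimated cell numbers given in the labels, 1083, 1076, 710, 1319, 571 and 2674. The labels call the 2 libraries of each group biological replicates and do not say how the sorted fractions were divided between them.

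Cells were kept with at least 300 detected genes and at most 20% mitochondrial UMIs, and 55 doublets (0.87% of 6323) called per library with Scrublet in scanpy 1.11.5 were left out. Counts were scaled to 10000 UMIs per cell and log-transformed. From 2000 variable genes, without Gja1, mitochondrial, ribosomal protein, sex-linked, haemoglobin, immediate early and heat shock genes, 30 principal components and 15 neighbours were computed. Leiden clustering (leidenalg 0.10.2, resolution 1, fixed seed) without batch integration gave 18 clusters. Clusters were named by marker lists written before the data were examined: a class needed a mean relative marker level of at least 0.25, at least 3 markers detected in 10% of cells or more, and no more markers of other classes than of its own among its 10 leading genes. These thresholds were chosen after the data were seen. There were 5 endothelial-like, 3 astroglial-like and 5 oligodendrocyte-like clusters and 2 without a name. The unnamed clusters were left out, which removed 4.13% of the cells of control replicate 1, all from a cluster led by Plvap, Igfbp3 and Esm1, and at most 1.28% of any other library. Cells with more UMIs of erythroid, microglial or leukocyte markers than of their own class were left out as well, at most 0.815% of a library. Class names carry "-like" because they rest on RNA alone.

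UMI counts were summed per library over the cells of a class, for libraries with at least 20 such cells. Endothelial-like sums were tested with edgeR 4.0.16 (R 4.3.3) after filterByExpr and TMM scaling, by the quasi-likelihood F test on all 6 libraries with group as the only term, and with the Benjamini-Hochberg adjustment at 0.05. The fit had 3 residual degrees of freedom and a biological coefficient of variation of 17.5%. Its p-values rest mostly on a spread pooled over genes, so those of called genes are far smaller than 3 degrees of freedom alone would give. The standard errors given are the absolute log2 fold change divided by the square root of the F statistic, so they rest on the same pooled spread. Both say little about the spread of a single gene between libraries. The sums ranged from 38787 UMIs in ECiKO replicate 2 to 2324700 in control replicate 1, so the libraries numbered 1 carry most of the information. DESeq2 1.42.0 was run beside it. Data were simulated with the same depths and with changes only in genes of at least 20 CPM. There edgeR recovered 15% of 2-fold and 83% of 4-fold changes between ECiKO and control. Between GlastiKO and control it recovered 22.2% and 95%, with 2 false calls in each set. Apart from these changes all simulated libraries shared the same gene means, so recovery in weaker genes or with a difference between the library numbers was not measured.

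Genes are named by a rule fixed beforehand: Gja1 in each comparison, and up to 10 genes per direction with an adjusted p under 0.05, a mean of at least 20 CPM and libraries of the groups that do not overlap, without markers of other classes and unnamed gene models. Where fewer than 5 qualified, the list was filled to 5 by the smallest unadjusted p, and such genes are given as not passing. Of each gene list described, up to 4 genes are named. Some genes of the lists, and 1 test that rested on one of them, are not reported here. The 25 gene lists and 15 cell type marker lists were also fixed before the data were examined, and 24 gene lists and 4 marker lists had enough tested members. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and with the correlation estimated. Gene positions come from GENCODE release M21 on mm10.

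For astroglial-like and oligodendrocyte-like cells the libraries numbered 2 were compared by CPM ratios with exact intervals and no test. A gene counted as higher or lower from 100 UMIs and a ratio of 1.5, and was named when it kept that direction in each of the class's 2 deep clusters. List medians were set against 10000 random lists drawn in 20 expression bins. Shares of cells have Clopper-Pearson intervals and CPM values exact Poisson intervals, both at 95% and for counting error alone. The planned exact permutation test of the share of progenitor- and neuroblast-like cells is void, because the libraries numbered 1 hold 4, 6 and 2 neural-lineage cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used.

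Alternatives planned beforehand were DESeq2, its size factors in edgeR, no filter on low counts, the replicate number as a block, only the 4 libraries of the groups compared, each library left out in turn, doublets kept, a stricter cell filter (600 genes, 10% mitochondrial), Leiden resolutions 0.5 and 2, and thinning to equal depth. When a library is left out, its group's remaining library is assumed to vary like those of the other groups. Planned tests of astroglial-like and of progenitor- and neuroblast-like cells between groups were not run because 1 library per group at most had enough cells. The planned class by group test of Gja1 with library as a block has no residual degree of freedom on the 9 class sums with at least 20 cells, so it was fitted without the block.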

Results

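RNA was measured in single cells sorted from the brains of adult mice aged 8 to 12 weeks. Per the labels, the sorted cells were endothelial cells (CD31-positive, Glast-negative) and neural stem and progenitor cells (Glast-positive, CD31-negative), both without CD45, from cortex and from the subventricular zone, the wall of the lateral ventricle in which neural stem cells persist. The 6 libraries form 3 groups of 2. Control mice carry floxed alleles of Gja1, the gene of the gap junction protein connexin 43. In the group labelled GlastiKO the deletion is directed at cells that express Glast, and in the group labelled ECiKO at endothelial cells. The study's title concerns contacts between vessels and neural stem cells through connexin 43, so each knockout was compared with the control group in each cell class that the files could resolve. The libraries held 4056910 and 9775060 UMIs (unique molecules) in control replicates 1 and 2, 2642312 and 14859187 in GlastiKO replicates 1 and 2, and 1735247 and 5164001 in ECiKO replicates 1 and 2. Of 7433 deposited barcodes, 6268 were used as cells. The median depth per cell used was 3502.5, 8028, 3247, 10679, 2776 and 786 UMIs in the same order.

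The libraries numbered 1 consisted almost entirely of endothelial-like cells, and those numbered 2 of oligodendrocyte-like and astroglial-like cells, in all 3 groups. Endothelial-like cells, which carry Pecam1, Cldn5, Flt1 and Cdh5, made up 90.3% of control replicate 1 (677 cells; 95% Clopper-Pearson interval 87.9 to 92.3%), 90.8% of GlastiKO replicate 1 (446 cells) and 97.7% of ECiKO replicate 1 (390 cells). In the libraries numbered 2 they made up 4.80% (45 cells), 5.56% (66 cells) and 0.879% (22 cells) in the same order of groups. Astroglial-like cells, the class that holds Slc1a3, Aqp4 and Aldoc and to which both astrocytes and quiescent neural stem cells belong, made up 43.5%, 34.8% and 11.9% of control, GlastiKO and ECiKO replicate 2 (408, 413 and 297 cells). Oligodendrocyte-like cells, which carry the myelin gene Mbp, made up 47.5%, 50.4% and 71.0%. Pericyte-like cells (Rgs5, Vtn) made up between 1.504 and 6.72% of each library. The endothelial-like class was the only one with at least 20 cells in all 6 libraries and therefore the only one with a test between groups, in which each group sets 1 library of 390 to 677 such cells beside 1 of 22 to 66. The other classes had 1 usable library per group or an incomplete set, so their values carry counting error only and no p-value.

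**Figure D1:**
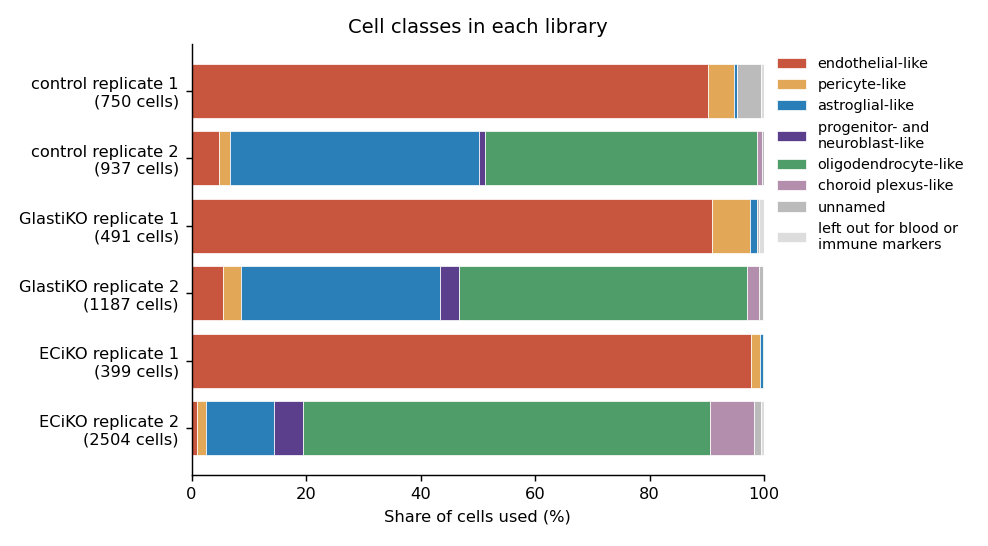
Share of the cells used (x axis, %) in each cell class, by colour, for the 6 libraries (y axis, with their numbers of cells). Endothelial-like cells make up 90.3 to 97.7% of the libraries numbered 1 and 0.879 to 5.56% of those numbered 2.

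Gja1, the targeted gene, was far more abundant in astroglial-like than in endothelial-like cells of the control group, and neither knockout label went with a lower level of it where the deletion was directed. In endothelial-like cells Gja1 was lowest in the control libraries, with 68.4 and 79.6 CPM (UMIs scaled to the UMI total of the class; 95% exact Poisson intervals 58.2 to 79.9 and 36.4 to 151, from 159 and 9 UMIs). It was at 141 and 131 CPM in the libraries labelled GlastiKO (217 and 28 UMIs) and at 236 and 206 CPM in the libraries labelled ECiKO (286 and 8 UMIs). Against control, Gja1 rose in the endothelial-like cells of the libraries labelled ECiKO by a log2 fold change of 1.70 ± 0.313 (SE, n = 2 libraries per group; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000711), opposite to the direction that the label names. Without control replicate 1 the log2 fold change was 1.65 (edgeR adjusted p = 0.788) and without ECiKO replicate 1 it was 1.32 (edgeR adjusted p = 0.662). For the libraries labelled GlastiKO the log2 fold change in endothelial-like cells was 1.01 ± 0.303 and did not pass (edgeR adjusted p = 0.558). With the cells of cluster 3, described below, the values were 1.29 (edgeR adjusted p = 0.0137) and 0.62 (edgeR adjusted p = 0.9996).

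In astroglial-like cells, where the Glast driver should act, Gja1 stood at 2555 CPM in control replicate 2 (4708 UMIs) and at 2500 CPM in GlastiKO replicate 2 (5390 UMIs), a ratio of 0.979 (95% exact interval 0.941 to 1.02). The ratio was 0.961 and 0.975 in the astroglial-like clusters 6 and 9 taken alone. In ECiKO replicate 2 it was at 2036 CPM (989 UMIs), a ratio to control replicate 2 of 0.797 (0.743 to 0.854) over the class, but of 1.02 and 0.95 in clusters 6 and 9. In this library 230 of the 297 cells of the class belonged to cluster 10, whose barcodes are shallow (median 704 UMIs). On mm10, Gja1 (ENSMUSG00000050953) lies on the plus strand of chromosome 10 from 56377330 to 56402513. The coding sequence of its full-length transcript (56387547 to 56388695) and the 3′ UTR (56388696 to 56390415) both lie in exon 2. The labels do not say which part the deletion removes, and 3′-end counting also counts a transcript that lost an upstream part only. Within the 3 libraries numbered 2, which hold enough cells of both classes, Gja1 was higher in astroglial-like than in endothelial-like cells by a log2 difference of 4.53 ± 0.336 (edgeR quasi-likelihood with library as a block, adjusted p = 2.80e-24, 2 residual degrees of freedom). In this test and the following fit the p-values rest mostly on the spread that edgeR pools over genes, not on the residual degrees of freedom. The difference between the classes in the knockout effect has no residual degree of freedom with the planned library block. Over the 9 class sums without that block, the ECiKO effect on Gja1 was higher in endothelial-like than in astroglial-like cells by 2.11 ± 0.596 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.056; unadjusted 0.000397) and the GlastiKO effect by 1.07 ± 0.583 (edgeR adjusted p = 0.9999; unadjusted 0.065), with 3 residual degrees of freedom, all from endothelial-like libraries. Without ECiKO replicate 1 the ECiKO value was 1.66 (edgeR adjusted p = 0.994) and without control replicate 1 it was 2.06 (edgeR adjusted p = 0.855). The test within the 3 libraries and the fit without the block were chosen after the values were seen.

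**Figure D2:**
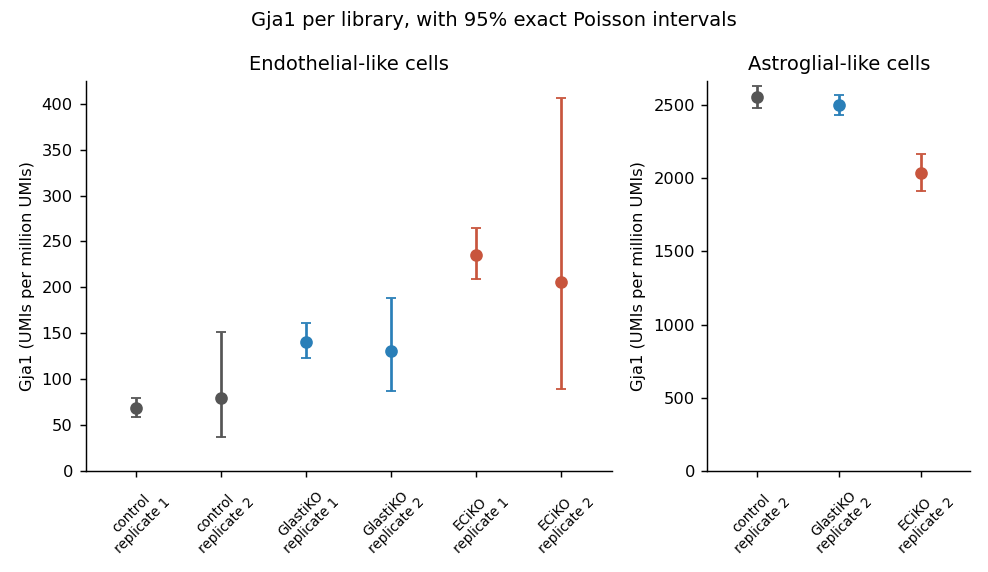
Gja1 in CPM (y axis) per library in endothelial-like cells (left) and astroglial-like cells (right; only libraries with at least 20 such cells), with 95% exact Poisson intervals as bars. In endothelial-like cells the control libraries are at 68.4 and 79.6 CPM and the libraries labelled ECiKO at 236 and 206 CPM.

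Besides Gja1, endothelial-like cells of the libraries labelled ECiKO had more Angpt2 than control cells. Angpt2 encodes angiopoietin 2, a ligand of the Tie2 receptor that endothelial cells release when vessels remodel. Its log2 fold change was 2.21 ± 0.476 (n = 2 libraries per group; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0192), with library values of 10.5 and 34.8 CPM in control and 63.0 and 22.8 CPM in ECiKO (CPM scaled by TMM here and below), so the groups overlap. Angpt2 lies on chromosome 8 from 18690263 to 18741562. It fell outside the naming rule and was singled out after its values were seen. Without control replicate 1 its log2 fold change was 0.81 (edgeR adjusted p = 0.998), without ECiKO replicate 1 it was 0.84 (0.924), and without ECiKO replicate 2 it was 2.32 (0.134). Without cluster 5, an endothelial-like cluster led by stress genes, it was 1.91 (0.9998). These 2 genes, Gja1 and Angpt2, were all that passed among 8493 genes tested with edgeR. At an unadjusted p under 0.05 there were 68 genes, where chance gives 424.7, and DESeq2 called 0. A count so far under chance means that the edgeR p-values ran large, as in the 2 other comparisons of groups (137 and 155 genes). The lack of further calls therefore does not show that other genes were unchanged. Cluster 3, led by Plvap, Igfbp3 and Esm1, was left out of the class, since its 10 leading genes held a marker of another class and none of endothelium. Endothelium was still its best class, with 11 markers detected and a relative marker level of 0.496, against 0.467 in cluster 1, which was kept. The kept clusters 2, 5 and 8 had no endothelial marker among their leading genes either, but none of another class. Of its 34 cells 31 came from control replicate 1 and none from ECiKO. With these cells in the class, a fit chosen after the results were seen, 19 genes were called, Gja1 and Angpt2 higher and 17 lower.

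Without cluster 3 no other gene passed. Of the genes with at least 20 CPM whose ECiKO and control libraries did not overlap, those with the smallest unadjusted p after Gja1 are named here. The Notch target Hey1, which specifies arterial identity, had a log2 fold change of 1.27 ± 0.372 (edgeR adjusted p = 0.9998) and Dll4, a Notch ligand gene of arteries and sprouts, one of 0.86 ± 0.301. Igfbp3, an insulin-like growth factor binding protein of sprouting vessels, was at 1.15 without cluster 3, which it leads, but at -2.31 with it (edgeR adjusted p = 1.79e-08), so its direction depends on those cells. The glycosyltransferase gene Galnt15 was at 0.97. Of the 5 named genes that were lower, Eln, the gene of elastin, which arterial endothelium makes, was at -2.30 ± 0.531 (edgeR adjusted p = 0.0524). Its control libraries themselves differed, with 32.4 and 199.8 CPM against 13.3 and 0 CPM in ECiKO, and it passed without control replicate 1 (-3.92; edgeR adjusted p = 2.07e-05) and with cluster 3 (-2.38; edgeR adjusted p = 0.00164). Ptgs2, the gene of the inducible cyclooxygenase, was at -1.39 and Car4, a carbonic anhydrase of capillaries, at -0.84. The centrosomal gene Cep295 was at -1.27 and the matrix gene Adamtsl2 at -1.19.

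As groups, immediate early and chaperone genes were called lower in endothelial-like cells of the libraries labelled ECiKO only at the preset inter-gene correlation. The median of each turned when 1 library was left out. Vessel-derived niche signals were higher only while cluster 3 was left out. Among 24 gene lists tested with camera, 3 passed at the preset inter-gene correlation and none with an estimated one. The immediate early genes, which dissociation induces within minutes, had a median log2 fold change of -0.133 over 23 genes (camera adjusted p = 0.00208; adjusted p = 0.902 with an estimated correlation). This list had 0 genes past the threshold over all genes and 0 adjusted over the list alone, and it turned to 0.175 without ECiKO replicate 2 (adjusted p = 0.00336), a library of 22 endothelial-like cells with 0 UMIs of Egr1, Fosb and Egr3. Heat shock and chaperone genes, led by Hspa1b, Hspa1a, Hsp90aa1 and Hspb1, had a median of -0.154 over 16 genes (camera adjusted p = 0.0242; adjusted p = 0.902 with an estimated correlation), with 0 genes called over all genes and 0 adjusted over the list alone. Without control replicate 1 their median was 0.110 (adjusted p = 0.872) and without ECiKO replicate 2 it was -0.078 (0.567). Vascular niche factors, secreted proteins such as those of Angpt2, Dll4, Igfbp3 and Ccn2 that vessels offer to neighbouring cells, had a median of 0.091 over 21 genes (camera adjusted p = 0.0242; adjusted p = 0.902 with an estimated correlation). In this list 1 gene was called over all genes and 3 adjusted over the list alone. The call ended without control replicate 1 (median 0.273, adjusted p = 0.215), without control replicate 2 (-0.00234, 0.201) and without ECiKO replicate 1 (-0.00958, 0.605). With cluster 3 it ended too, with camera ranking the list downwards (median 0.059, adjusted p = 0.610). The other 2 lists stayed called with cluster 3 (-0.242 and -0.222), and the immediate early call ended without control replicate 1 (-0.038, 0.148).

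The Notch pathway list had 0 genes called over all genes and 2 adjusted over the list alone (Hey1 and Dll4), with a median of -0.154 over 17 genes (camera adjusted p = 0.807). The other lists in this comparison did not pass, with camera adjusted p between 0.154 and 0.973 over 21 lists. Of the cell type marker lists, haemoglobin genes fell (median -1.10 over Hba-a2, Hbb-bs and Hba-a1; camera adjusted p = 0.0257; adjusted p = 0.465 with an estimated correlation; 0 called over all genes and 3 adjusted over the list alone). Astroglial markers (-1.24, 4 genes), oligodendrocyte markers (0.138, 3 genes) and endothelial markers (0.026, 12 genes) gave no call. Ribosomal protein genes fell, with 65 of 81 below 0 and a median of -0.148 (camera adjusted p = 0.0076; adjusted p = 0.626 with an estimated correlation), and the 13 mitochondrial genes gave no call (median 0.013).

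Endothelial-like cells of the libraries labelled GlastiKO had more RNA of 9 genes than control cells, among them the immediate early genes Egr3, Egr1 and Fosb, and none was called lower. With cluster 3 in the class 26 were called, 8 higher, 7 of them among these 9, and 18 lower. The immediate early list as a whole passed at the preset inter-gene correlation but not with an estimated one (adjusted p = 0.580). Egr3, a growth factor- and VEGF-induced transcription factor, rose by a log2 fold change of 2.39 ± 0.433 (n = 2 libraries per group; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000532), from 13.2 and 8.69 CPM to 80.1 and 38.2 CPM. Egr1, its relative, rose by 1.23 ± 0.288 (edgeR adjusted p = 0.0344), and the AP-1 gene Fosb by 1.18 ± 0.286 (edgeR adjusted p = 0.0446). Depp1, a FOXO target linked to oxidative stress and autophagy, rose by 1.56 ± 0.327 (edgeR adjusted p = 0.00547). Apold1, an immediate early gene of endothelium induced by hypoxia and injury, rose by 1.33 ± 0.285 (edgeR adjusted p = 0.00634), from 279 and 261 CPM to 907 and 425 CPM. In each of these 5 genes both GlastiKO libraries lay above both control libraries. Without GlastiKO replicate 1 none of them passed: the log2 fold changes were 1.55 for Egr3, 0.52 for Egr1, 0.64 for Fosb, 0.73 for Depp1 and 0.62 for Apold1 (edgeR adjusted p = 0.996 for each). Without control replicate 1 none passed either, with edgeR adjusted p between 0.478 and 0.928, and without control replicate 2 Egr3 alone of them did (edgeR adjusted p = 0.0103; Depp1 0.0569, Apold1 and Egr1 0.484, Fosb 0.9999). With cluster 3 Egr1 (0.88, edgeR adjusted p = 0.380) and Fosb (0.77, edgeR adjusted p = 0.837) did not pass. Cluster 5, led by Klf2, Apold1, Hspb1, Ier2 and Junb among others, held 92 of the 446 endothelial-like cells of GlastiKO replicate 1 and 95 of the 677 of control replicate 1. It was set apart after the results were seen because such genes lead it, though immediate early and heat shock genes did not enter the clustering. Without its cells 1 gene was called in place of 9, none of these 5: the log2 fold changes were 1.06 for Depp1, 0.91 for Apold1, 0.54 for Egr1 and 0.91 for Fosb (edgeR adjusted p = 0.9999 for each), and Egr3 fell under the low-count filter. From the 4 libraries of GlastiKO and control alone, Egr3 was the 1 call (edgeR adjusted p = 0.0135; Depp1 0.0693, Apold1 0.112, Egr1 and Fosb 0.175). Egr3 lies on chromosome 14 from 70077203 to 70082614.

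The other 4 genes called for GlastiKO fell outside the naming rule, and they were singled out after their values were seen. Angpt2 had a log2 fold change of 2.34 ± 0.447 (edgeR adjusted p = 0.00108), from 86.5 and 9.54 CPM in GlastiKO against 10.5 and 34.8 CPM in control. It turned to -0.45 without GlastiKO replicate 1 (edgeR adjusted p = 0.996) and was 0.93 without control replicate 1 (0.999), so it rests on the libraries numbered 1. Adamts9, a secreted protease of vessel walls, had 1.97 ± 0.403 (edgeR adjusted p = 0.00416) and 1.09 without control replicate 1 (0.999). Without GlastiKO replicate 1 it fell under the low-count filter. Ch25h, which makes 25-hydroxycholesterol and answers inflammatory signals, had 2.36 ± 0.569 (edgeR adjusted p = 0.0431) and 2.27 without control replicate 2 (0.0821). Slc1a3, the astroglial gene of Glast itself, had 2.64 ± 0.633 (edgeR adjusted p = 0.0431), with 7.31 and 0 CPM in control and 23.6 and 90.7 CPM in GlastiKO, and it passed in no fit that left out 1 of these 4 libraries (edgeR adjusted p from 0.0812 to 0.999, with log2 fold changes of 1.78 to 3.77 where the control kept counts). Without cluster 5, Ch25h was the 1 gene called (2.68, edgeR adjusted p = 0.0448), with Angpt2 at 1.44, Adamts9 at 0.68 and Slc1a3 at 2.37 (0.9999 for each), and from the 4 libraries of the 2 groups alone none of these 4 passed (Ch25h fell under the filter). In all, 9 of 8493 genes passed in edgeR, 137 had an unadjusted p under 0.05 where chance gives 424.7, and DESeq2 called 0.

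Without cluster 3 no gene was called lower in the libraries labelled GlastiKO. The 5 lower genes with the smallest unadjusted p, among those of at least 20 CPM whose libraries did not overlap, were the reductase gene Cyb5r1 (log2 fold change -1.27 ± 0.411, edgeR adjusted p = 0.812), Zbtb21 (-1.21), Eln (-1.20), the cohesin regulator Pds5b (-0.79) and the adhesion scaffold Git2 (-0.73). Eln passed without control replicate 1 (-2.84, edgeR adjusted p = 0.00176).

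**Figure D3:**
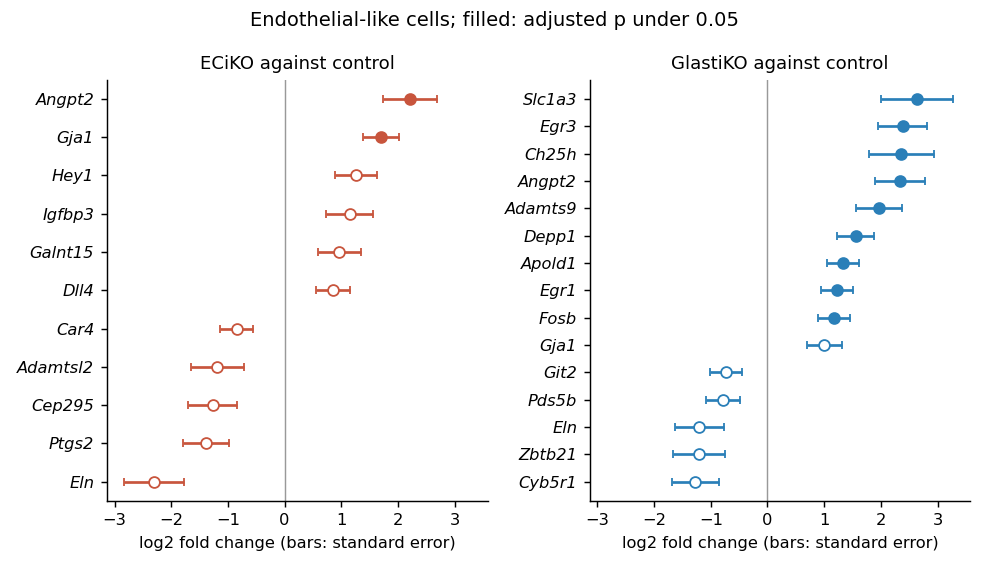
Log2 fold changes (x axis) with standard errors as bars for the genes named in endothelial-like cells (y axis), ECiKO against control on the left and GlastiKO against control on the right, n = 2 libraries per group. Filled points passed in edgeR: 2 genes on the left and 9 on the right. The standard errors rest mostly on the spread that edgeR pools over genes.

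As groups, immediate early, growth factor signalling, inflammatory and energy metabolism genes were called higher in GlastiKO endothelial-like cells only at the preset inter-gene correlation. The lists share genes, such as Egr1 and Nfkbia, so their calls are not independent. Of 24 lists, 6 rose and none fell at the preset correlation, and none passed with an estimated one. Immediate early genes, led by Egr1, Fosb, Nr4a1 and Fos, had a median log2 fold change of 0.503 with 21 of 23 above 0 (camera adjusted p = 4.52e-11; adjusted p = 0.580 with an estimated correlation). In this list 2 genes were called over all genes and 3 adjusted over the list alone. The call ended without GlastiKO replicate 1 (median 0.194, adjusted p = 0.302) and held with cluster 3 at a median of 0.213. MAPK and EGF receptor signalling, with Egr1, Ccnd1 (1.05) and the feedback inhibitors Spry4 (1.43) and Spry1, had a median of 0.322 over 13 genes (camera adjusted p = 0.0017; adjusted p = 0.580 with an estimated correlation; 1 gene over all genes and 3 adjusted over the list alone). It was not called without control replicate 1 (median -0.069, adjusted p = 0.409), without GlastiKO replicate 1 (0.247, 0.927) or with cluster 3 (0.130, 0.257). Vascular niche factors, with Angpt2, Ccn1, Ccn2 and Edn3, had a median of 0.219 over 21 genes (camera adjusted p = 0.00137; adjusted p = 0.580 with an estimated correlation; 1 gene over all genes and 4 adjusted over the list alone), and were not called without control replicate 1 (0.362, adjusted p = 0.0503) or GlastiKO replicate 1 (-0.030, 0.780), nor with cluster 3, where camera ranked them downwards (0.117, 0.641). Inflammatory activation, with Ch25h, Vcam1, Nfkbia and Nfkbiz, had a median of 0.271 over 14 genes (camera adjusted p = 0.00769; adjusted p = 0.580 with an estimated correlation; 1 gene over all genes and 1 adjusted over the list alone). Without GlastiKO replicate 1 its median was -0.308 (adjusted p = 0.438), without control replicate 1 it was 0.274 (0.976) and without control replicate 2 it was 0.269 (0.104), and with cluster 3 it was 0.164 (0.078).

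The respiratory chain genes encoded in the nucleus, led by Uqcrq, Cox5b and Ndufa2, had a median of 0.193 with 26 of 35 above 0 (camera adjusted p = 0.00312; adjusted p = 0.636 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone), and were not called without control replicate 1 (0.081, adjusted p = 0.409) or GlastiKO replicate 2 (0.046, 0.932), nor with cluster 3 (0.111, 0.078). Glycolysis genes had a median of 0.307 with 13 of 15 above 0, led by Ldha (0.82), Aldoa, Pgk1 (0.60) and Tpi1 (camera adjusted p = 0.00428; adjusted p = 0.580 with an estimated correlation; 0 over all genes and 1 adjusted over the list alone). They were not called without control replicate 1 (0.349, adjusted p = 0.254) or GlastiKO replicate 1 (0.375, 0.184). Ribosomal protein genes rose too, 75 of 81 above 0 with a median of 0.189 (camera adjusted p = 6.92e-06; adjusted p = 0.757 with an estimated correlation), as did the astroglial markers, with a median of 0.967 and 3 of 4 above 0 (camera adjusted p = 0.0071; adjusted p = 0.541 with an estimated correlation), of which Slc1a3 was the 1 gene called, both over all genes and adjusted over the list alone. Mitochondrial genes gave no call (median 0.068), nor did haemoglobin (-0.058), oligodendrocyte (-0.092) or endothelial markers (-0.059). The other 18 lists did not pass, with camera adjusted p between 0.0744 and 0.891. For cholesterol synthesis the median was -0.089 while camera ranked the list upwards (adjusted p = 0.826).

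The knockouts were also compared directly in endothelial-like cells. No gene passed between the libraries labelled ECiKO and GlastiKO (0 of 8493 in edgeR, 0 in DESeq2, 155 at an unadjusted p under 0.05). The edgeR count was 5 without GlastiKO replicate 1, 3 without GlastiKO replicate 2, 10 without ECiKO replicate 1 and 1 with cluster 3. A gene called in only 1 of the comparisons with control was therefore not shown to differ between the knockouts.

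Cholesterol synthesis genes were higher in astroglial-like cells of GlastiKO replicate 2 than in those of control replicate 2, the libraries of these groups with enough such cells. Of 20 such genes, 19 were higher, with a median log2 ratio of 0.376 against 0.078 for random lists of equal expression (percentile 99.97 of 10000), and 0.340 and 0.266 in clusters 6 and 9 alone. Hmgcs1, the HMG-CoA synthase gene of the pathway, had a CPM ratio of 1.61 (95% exact interval 1.41 to 1.84), Sqle, the squalene epoxidase gene, 1.53 (1.30 to 1.80), and Srebf2, the pathway's transcription factor, 1.503 (1.28 to 1.77). In clusters 6 and 9 the ratios were smaller, 1.435 (1.17 to 1.77) and 1.29 (1.03 to 1.61) for Hmgcs1, 1.35 (1.06 to 1.735) and 1.26 (0.955 to 1.65) for Sqle and 1.27 (0.992 to 1.64) and 1.42 (1.09 to 1.86) for Srebf2, so the interval of Sqle in cluster 9 and that of Srebf2 in cluster 6 include 1. In ECiKO replicate 2 the same list had a median of -0.146 over the class but of 0.103 and -0.133 in clusters 6 and 9, with Hmgcs1 at 1.26 (1.009 to 1.557) and Sqle at 0.603 (0.417 to 0.852). In clusters 6 and 9 Hmgcs1 was at 1.444 (1.03 to 2.003) and 1.19 (0.754 to 1.802) there, and Sqle at 0.499 (0.261 to 0.884) and 0.498 (0.197 to 1.05). The Hmgcs1 ratio in cluster 6 was thus similar in both knockouts. The intervals cover counting error between 2 libraries, not the spread between mice.

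**Figure D4:**
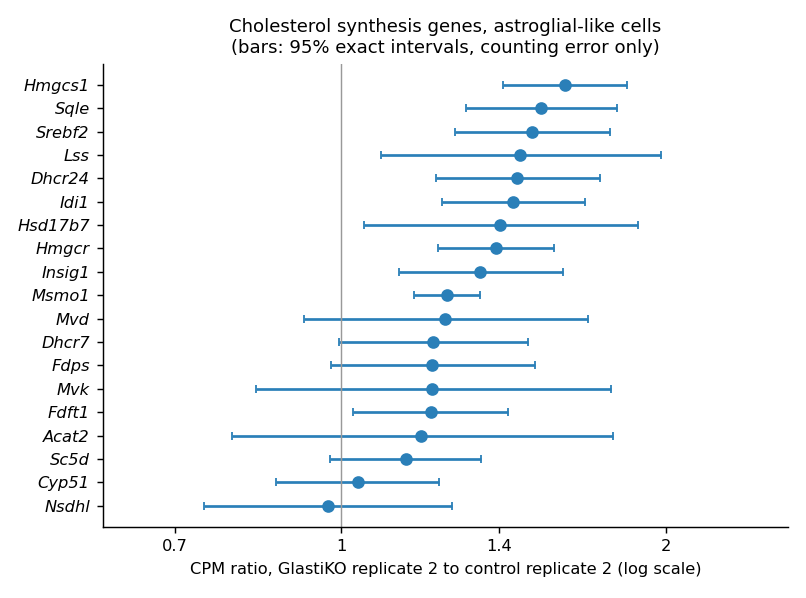
CPM ratio of GlastiKO replicate 2 to control replicate 2 in astroglial-like cells (x axis, log scale) for 19 of the 20 cholesterol synthesis genes of the list (y axis), with 95% exact intervals for counting error as bars. Of the genes shown, 18 lie above a ratio of 1, with Hmgcs1 highest of those shown at 1.61.

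Of the other genes in GlastiKO astroglial-like cells, the Notch effector Hes5, which keeps neural stem cells undifferentiated, was lower, at a ratio of 0.614 (0.557 to 0.678), and 0.607 and 0.555 in clusters 6 and 9. The Notch pathway list had a median of -0.127 (percentile 2.26). Cluster 6 made up 27.0% of clusters 6 and 9 in control replicate 2 and 68.98% in GlastiKO replicate 2, so ratios over the class also carry this mix. Lower over the class and, by less, within clusters 6 and 9 were the Wnt modulator Sfrp5 (0.161, 0.106 to 0.237; 0.334 and 0.375 in the clusters), the membrane protein gene Igsf1 (0.235; 0.389 and 0.601) and the elastic fibre gene Fbln5 (0.230; 0.5003 and 0.388). Lower as well were the lipid genes Angptl4 (0.372) and Pltp (0.407) and the potassium channel gene Kcnj16 (0.532). Higher were Ranbp3l (3.77, 2.92 to 4.93; 2.064 and 2.099 in clusters 6 and 9), which exports SMAD proteins of the BMP pathway from the nucleus, the dystroglycan-complex gene Drp2 (2.23), the elongation factor gene Aff1 (2.04), Nat8f4 (1.95), the calcium channel gene Cacnb1 (2.01), Zfp865 (1.94) and Efs (1.82). The Y-linked gene Eif2s3y was lower (0.304). In all, 369 of 6244 genes with at least 100 UMIs had a ratio of at least 1.5 and 203 of at most its inverse, of which 43 and 25 kept it in both clusters 6 and 9. Slc1a3, the gene of Glast, was at 0.679 (0.652 to 0.707) over the class and at 0.537 and 0.506 in clusters 6 and 9. It was singled out after its values were seen. Respiratory chain genes had a median of 0.175 (percentile 96.2; 0.256 and -0.024 in clusters 6 and 9), MAPK and EGF receptor genes 0.33 (percentile 99.4; -0.076 and 0.204), and ribosomal protein genes 0.512 (0.164 and 0.013), so these lists differ between clusters.

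In astroglial-like cells of ECiKO replicate 2, the imprinted gene Nnat, expressed in neural progenitors, was lower than in control replicate 2 at a ratio of 0.276 (0.213 to 0.352), with 0.296 and 0.315 in clusters 6 and 9. For the other genes the ratio over the class is followed by those in clusters 6 and 9, since 230 of the 297 cells lie in cluster 10. The sarcosine oxidase gene Pipox was at 0.107 (0.0287 to 0.280, from 4 UMIs; 0.157 and 0.0890), Sfrp5 at 0.184 (0.598 and 0.0693), the tubulin glycylase gene Ttll3 at 0.230 (0.325 and 0.164), Cd38 at 0.259 (0.449 and 0.560), Igsf1 at 0.274 (0 and 0.593) and Fbln5 at 0.0703 (0.0084 to 0.260, from 2 UMIs; 0 and 0.219). Higher were Gabra2, a GABA receptor subunit (2.09, 1.52 to 2.85; 1.77 and 2.81), and the Toll-like receptor and TGF-beta signalling kinases Irak2 (1.67, 1.15 to 2.40; 1.54 and 3.10) and Map3k7 (1.68, 1.14 to 2.44; 1.71 and 1.86). Tmem56 (1.501) and Pogz (1.54) were higher with intervals that include 1. Xist was at 0.002 (1 UMI) and Eif2s3y at 2.13, so the ratios of this library to control may also carry a difference in sex. Of 3972 genes, 440 had a ratio of at least 1.5 and 425 of at most its inverse, and 27 and 71 kept it in both clusters. The class sum of this library carried oligodendrocyte RNA, with Mbp at 659 CPM against 26.6 CPM in control, so list medians over the class are read beside clusters 6 and 9. Neural stem cell quiescence genes had a median of -0.347 (0.011 and -0.298 in clusters 6 and 9), activation and cell cycle genes 0.338 (-0.218 and -0.007), Notch genes -0.495 (-0.004 and -0.307) and BMP and TGF-beta genes -0.548 (-0.018 and -0.247).

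The class of progenitor- and neuroblast-like cells, which holds Top2a, Sox11 and Dcx, was counted as a share of all neural-lineage cells. This is the measure closest to neurogenesis that the design allows. Whether the class lies wholly past the stem cell stage was not tested, and it also held markers of oligodendrocyte precursors. Progenitor- and neuroblast-like cells were 10 of 418 neural-lineage cells in control replicate 2, or 2.39% (95% Clopper-Pearson interval 1.15 to 4.36%). They were 39 of 452 in GlastiKO replicate 2, or 8.63% (6.21 to 11.6%), and 125 of 422 in ECiKO replicate 2, or 29.6% (25.3 to 34.2%). The ECiKO share was 57.3% (59 of 103 cells) with the stricter cell filter, which removes most cells of the shallow cluster 10, and 42.7% (125 of 293) at Leiden resolution 2, against 2.94% and 2.39% in control replicate 2. In the libraries numbered 1 they were 1 of 4, 0 of 6 and 0 of 2 cells, which allows no share to be read. The planned permutation test over both libraries of a group is therefore void, because 1 of 4 cells in control replicate 1 sets its outcome, and no test of the share is given. Within the class, the proliferation genes Top2a and Mki67 were at 1024 and 493 CPM in control replicate 2, 639 and 412 CPM in GlastiKO replicate 2 and 1063 and 697 CPM in ECiKO replicate 2. The migrating-neuroblast gene Dcx was at 202, 639 and 310 CPM and Sox11 at 1779, 3262 and 2777 CPM in the same order. The contents of the class differed as well, with markers of oligodendrocyte precursors at 2825, 1029 and 922 CPM, astroglial markers at 2361, 739 and 1070 CPM and oligodendrocyte markers at 179, 304 and 1957 CPM, so these values do not compare like cells, and control rests on 10 cells.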

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

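Apart from the comparison of the summed oligodendrocyte markers and the class by group test of Gja1, which was planned with a library block and run without it, the tests in this part were chosen after the results they address were seen.

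Gja1 was higher, not lower, in endothelial-like cells of the libraries labelled ECiKO, while in astroglial-like cells its CPM ratio to control was 0.797 for ECiKO and 0.979 for GlastiKO, both on the other side of 1 from every endothelial-like library pair. The astroglial-like values show no clear fall: the GlastiKO interval (0.941 to 1.02) includes 1, and the ECiKO ratio was 1.02 and 0.95 in clusters 6 and 9 and 1.01 without the shallow cluster 10. The effect in endothelial-like cells exceeded that in astroglial-like cells by a log2 difference of 2.11 for ECiKO (edgeR quasi-likelihood without a library block, adjusted p = 0.056; unadjusted 0.000397) and 1.07 for GlastiKO (edgeR adjusted p = 0.9999), neither past the threshold after adjustment. The tables argue against astroglial RNA as the source, since ECiKO replicate 1 carried 0.1% of the excess of astroglial markers that such RNA would bring (1.9 CPM seen, 2034.8 CPM needed). They also argue against another mix of the endothelial-like clusters 0, 1, 2 and 5. The ratio of ECiKO replicate 1 to control replicate 1 was 3.22 with the control mix of these and 3.45 without that correction. Cluster 3, with 31 of its 34 cells from control replicate 1, did not enter this count. With its cells in the class the rise was smaller, as given above, so its part in the difference stays open. An exchange of the control and ECiKO labels stays open, because it would put Gja1 in GlastiKO above the libraries labelled control, where the log2 fold change was 1.01 but did not pass (edgeR adjusted p = 0.558). Also open and untested are transcripts of the deleted allele that keep their 3′ end, and a true rise of Gja1 with the genotype.

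The libraries numbered 1 and 2 differ in cell classes in the same way in each group, although the labels call them biological replicates. A candidate explanation is that the numbers name the separately sorted fractions, which would also make the free RNA around the cells differ. The planned comparison of the summed oligodendrocyte markers in endothelial-like cells, library numbered 2 to library numbered 1, gave a smallest ratio of 1.7 over the groups, under the bound of 2 set for excluding the explanation, but that bound was wrong: Mal, which endothelial-like cells express themselves, made up 409 of the 428 CPM of the sum in control replicate 1. In GlastiKO and ECiKO replicate 1 Mal made up 521.8 of 539.9 and 445.2 of 462.5 CPM. In the libraries numbered 2 it made up 548.5 of 990.8 CPM (control), 686.0 of 933.4 CPM (GlastiKO) and 593.0 of 1650 CPM (ECiKO). The rest of the sum was thus higher in the library numbered 2 of each group. These libraries hold nearly all oligodendrocyte-like cells, so more of their free RNA follows from the cell make-up, whatever its cause. The comparison therefore cannot decide for or against the explanation. The sum without Mal was not planned. Xist was at 589.5 CPM in ECiKO replicate 1 and 0.194 CPM in ECiKO replicate 2, so these were not 2 fractions of the same mice. Fractions sorted from different mice are not excluded by this, and the explanation stays open. If it holds, the 2 libraries of a group are no replicates of a class: each edgeR p in endothelial-like cells then rests on a library sorted for them and on 22 to 66 such cells of the other fraction, and n = 2 libraries per group does not measure the spread between mice. No biological explanation was tested for this pattern.

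The share of progenitor- and neuroblast-like cells was higher in ECiKO and GlastiKO replicate 2 than in control replicate 2. For ECiKO, cells under 1000 UMIs, most of the 422 neural-lineage cells, were left out and the others thinned to that depth. The share was then 38.3% (49 of 128 cells, interval from 29.8%) against 2.23% in control (up to 4.197%). The high share was thus not confined to shallow barcodes. This cannot exclude depth as a cause, because the cut favours cells with more RNA and can itself raise the share. In control replicate 2 progenitor- and neuroblast-like cells had a median of 12149 UMIs and astroglial-like cells one of 3753.5. The tables argue against another mix of astroglial-like clusters for ECiKO, since the share counted with clusters 6 and 10 alone was 32.1% (from 27.4%) against 7.75% (up to 13.8%). For GlastiKO the mix may account for the difference, since the same count gave 11.9% (from 8.62%), whose interval overlaps that of control. The spread between mice, their sex and the sorting remain open next to the genotype, because each group has 1 such library. For ECiKO the depth of the cells stays open as well. Xist was at 0.194 CPM in ECiKO replicate 2, 454.5 CPM in control replicate 2 and 670.2 CPM in GlastiKO replicate 2.

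In the libraries labelled ECiKO, nuclear-encoded respiratory chain genes had a median log2 ratio to control of 0.297 in astroglial-like cells and 0.084 in oligodendrocyte-like cells, while each endothelial-like library pair went the opposite way. In the deep clusters the medians were 0.247 and -0.101 (astroglial-like clusters 6 and 9) and -0.065 and -0.028 (oligodendrocyte-like clusters 11 and 12), so the contrast holds in the deep astroglial-like cluster 6 but in none of the other 3. The difference between classes was not tested. In oligodendrocyte-like cells of the libraries labelled GlastiKO, immediate early genes had a median log2 ratio of -0.783 (-0.46 and -1.084 in clusters 11 and 12), opposite to each endothelial-like library pair, and this difference was not tested either. Choroid plexus-like cells, which no comparison used, made up 7.79% of ECiKO replicate 2 (0.854% in control replicate 2), and oligodendrocyte-like cells 71.0% (47.5% in control replicate 2). Neither class belongs to the sorted populations that the labels name, and whether these differences exceed the spread between mice was not tested.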

How the results depend on the processing

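The alternatives chosen only after the results were seen are the fits without the endothelial-like cluster led by stress genes, those with cluster 3, those with robust dispersion estimates, the values without the shallow astroglial-like cluster 10, the share over libraries with at least 20 neural-lineage cells, and the class by group fits without a library block.

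The count of genes called for ECiKO against control (2) was 0 with DESeq2 and 0 after thinning all libraries to the smallest total, and between 1 and 4 when 1 library was left out, with Gja1 the only call without ECiKO replicate 2, and 19 with cluster 3 (17 lower). For GlastiKO against control (9) it was 0 with DESeq2, 0 after thinning, 1 from the 4 libraries of the 2 groups alone, 1 without the stress-led cluster, 26 with cluster 3 (18 lower), and between 3 and 13 when 1 library was left out. For ECiKO against GlastiKO (0) it was 1 with the size factors of DESeq2, 1 with doublets kept, 1 with the stricter cell filter, 1 with robust dispersion, 1 with cluster 3 and between 0 and 10 when 1 library was left out. Without control replicate 1, 0 of the main calls were shared in either comparison with control, and the same held without ECiKO replicate 1 and without GlastiKO replicate 1. Thinning leaves each library as few UMIs as ECiKO replicate 2 has; cluster 3 adds cells to control almost alone; the other causes were not tested.

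With the replicate number as a block, 4 genes were called for ECiKO, 21 for GlastiKO (8 of the 9 shared) and 9 between the knockouts, and Gja1 in GlastiKO passed at a log2 fold change of 1.05 (edgeR adjusted p = 0.0193). The last result is what an exchange of the control and ECiKO labels would bring, and the exchange stays open under either fit. Residuals gave no sign that the numbers pair the libraries, with correlations across genes of 0.089, 0.063 and 0.060 between the differences of 2 groups. This check is weak, because the libraries numbered 2 hold 22 to 66 endothelial-like cells and counting error lowers such correlations. The numbers do go with the cell make-up of the libraries in each group. The block was left out of the main fits, and whether it belongs there is not settled.

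Gja1 in endothelial-like cells of ECiKO stayed above control in each alternative run. It was 1.65 with DESeq2 (adjusted p = 1.0) and 2.24 after thinning (edgeR adjusted p = 0.9995), neither past the threshold, and 1.32 to 1.81 when 1 library was left out. In GlastiKO it was 0.84 to 1.09 when 1 library was left out. In astroglial-like cells the ECiKO ratio of 0.797 moved to 1.05 with the stricter cell filter, 1.01 at Leiden resolution 2 and 1.01 without cluster 10. The first 2 took 223 and 129 of the 230 cells of cluster 10 out of the class. The GlastiKO ratio stayed within its interval.

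The numbers of gene lists called, 3 for ECiKO and 6 for GlastiKO, were 0 and 0 with an estimated correlation, 3 and 3 with cluster 3, and 0 to 6 and 1 to 10 when 1 library was left out. Medians reversed for ECiKO in immediate early genes without ECiKO replicate 2 (0.175, the highest of a range from -1.86 without ECiKO replicate 1), in heat shock genes without control replicate 1 (0.110, range from -1.08) and in vascular niche factors without ECiKO replicate 1 (-0.00958, range up to 0.273) and control replicate 2 (-0.00234). For GlastiKO, leaving out GlastiKO replicate 1 reversed inflammatory activation (-0.308, range up to 0.487), the median of vascular niche factors (-0.030), the camera direction of the MAPK and EGF receptor list (median 0.247; -0.069 without control replicate 1, range up to 0.311) and Angpt2 (-0.45, range up to 2.76). After thinning, Apold1 was at -0.50 and Egr1 at -0.078. The cause was not tested. With cluster 3 Igfbp3 in ECiKO reversed (-2.306), as did the camera direction of vascular niche factors (medians 0.059 for ECiKO and 0.1172 for GlastiKO).

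The mean shares over both libraries of a group are set by 1 of 4 neural-lineage cells in control replicate 1, so their changes say nothing about stability. The ECiKO difference in the share of progenitor- and neuroblast-like cells (1.11 points) ranged from -13.7 to 15.9 when 1 library was left out, with -10.2 among the reversed values. The GlastiKO difference (-9.38 points) turned to 2.90 after thinning cells and to 6.24 over libraries with at least 20 neural-lineage cells (27.2 for ECiKO), and ranged from -20.7 to 1.92 when 1 library was left out.

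Over the 72 single genes and lists followed, 645 of 766 alternative values kept their direction and side of the threshold, 84 lost a call, 26 gained one and 11 reversed. Most of the 72 had no call in the main fit to lose: of 24 lists, 3 were called for ECiKO and 6 for GlastiKO. Staying uncalled counts as kept, so the 645 values do not measure how stable the calls are. Some genes gave no value because they fell under the low-count filter, among them Adamts9 without GlastiKO replicate 1, Ch25h without that library or control replicate 1, and Egr3 without the stress-led cluster. The class by group difference of Gja1, fitted without the planned library block, kept its direction and stayed short of the threshold in each alternative run (1.66 to 2.06 for ECiKO and 0.908 to 1.04 for GlastiKO when 1 library numbered 1 was left out). Without a library numbered 2 of the groups compared it has no value. Alternatives for the tests of astroglial-like and progenitor- and neuroblast-like cells were not run, since those tests had no replicates. On simulated data with these depths and library numbers together, 15% and 22.2% of 2-fold and 83% and 95% of 4-fold changes were recovered. The changed genes there had at least 20 CPM, and depth was not varied on its own.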

Other observations

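The values in this part were chosen after the data were seen, and none was tested. Oligodendrocyte-like cells of GlastiKO replicate 2 had less RNA of immediate early and heat shock genes than those of control replicate 2. The CPM ratio was 0.271 for Fosb (95% exact interval 0.225 to 0.327), 0.384 for Fos, 0.387 for Egr1, 0.414 for Junb, 0.440 for Ier2, 0.405 for Hspa1a and 0.434 for Hspa1b. The histone genes Hist1h4d (2.15) and Hist1h1c (1.94) and the actin gene Actg1 (1.68) were higher. In ECiKO replicate 2 the protease gene Klk6, a marker of 1 type of mature oligodendrocyte, was higher (2.83, 2.54 to 3.15; 2.45 and 2.68 in clusters 11 and 12), as was the stress-hormone-induced kinase gene Sgk1 (1.70; 1.62 and 1.61), and Hspa1b (0.394; 0.324 and 0.252 in clusters 11 and 12) and Hspa1a (0.420; 0.475 and 0.173) were lower. The class ratios of this library also carry its cell mix. Of its 1779 oligodendrocyte-like cells 1009 and 605 were in the shallow clusters 13 and 16 (median 720 and 772 UMIs), while 274 and 135 of the 445 in control replicate 2 were in clusters 11 and 12.

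ECiKO replicate 2 held 1 UMI of Xist (0.194 CPM) and 124 CPM of the Y-linked gene Ddx3y, while the other 5 libraries held both, with Xist between 308 and 670 CPM and Ddx3y between 16.8 and 68.9 CPM. The sex of the mice is not in the labels. Comparisons between the libraries numbered 2 may therefore also carry a difference in sex.

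The astroglial-like clusters differed in their shares between libraries. Cluster 6, led by Lhx2, Grin2c and Dkk3, made up 27.0% (95% Clopper-Pearson interval 22.7 to 31.7%) of clusters 6 and 9 together in control replicate 2, 68.98% (64.2 to 73.5%) in GlastiKO replicate 2 and 52.2% (39.7 to 64.6%) in ECiKO replicate 2. Cluster 9 was led by Agt, Gria1 and Slc6a11, of which Agt and Slc6a11 are known from astrocytes outside the cerebral cortex.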
